A study of Mus musculus with 4 samples.

How the data were processed

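Chromatin accessibility was measured by single-nucleus ATAC-seq (transposase insertion read in single nuclei on a droplet platform) in dissociated liver of C57BL/6 mice. There were 2 libraries from mice of 24 months (old replicates 1 and 2) and 2 from mice of 6 months (young replicates 1 and 2). Per the series description, the digestion was meant to enrich the fibrotic niche. The letters that the labels put before each replicate number are not explained in the sources used here. The labels give 1 library per replicate number and do not say whether a library comes from 1 animal.

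Per the file headers and the labels, the authors processed each library with Cell Ranger ATAC 2.1.0 on genome build mm10. The deposited matrix of each library holds raw counts of transposase cut sites per peak and barcode, with no normalization. Between 89.8% and 91.0% of the nonzero values per library were even numbers, as when both ends of a fragment fall in a peak. Other deposited fields were of other units, that is, text and coordinates: the peak start and end per library, the barcodes, and a table of the authors with a cell type and an age per nucleus. How the authors made that annotation is not given in the sources used here. It held 9524 nuclei of old replicate 2, 4132 of young replicate 1 and 8721 of young replicate 2, and none of old replicate 1. Of these, 8613, 3485 and 6680 matched a barcode of the matrix, and 911, 647 and 2041 did not and were not used here. A further pair of deposited peak lists with values in a score column was not used here because their coordinates are not those of mouse.

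Peaks were called by the authors per library, so counts were first put on common regions. Touching or overlapping peaks on the standard chromosomes were merged into 250338 regions. The 109525 regions with a peak of every library (43.8%) were tested, since a library without a peak in a region has no count there. These regions held between 90.7% and 93.7% of a library's counts. Gene counts were sums over the tested regions that overlap a gene body or lie within 2 kb of it, for protein-coding genes of the RefSeq annotation of GRCm38.p6, the assembly behind mm10. The plan was to use only the 2 kb upstream, but the annotation gives no strand, so both sides were used. Of 21887 genes, 16409 had a tested region, and 4.64% of the regions counted for 2 or more genes. Coordinates are 1-based on mm10.

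Cell types of old replicate 2 and of both young libraries were those of the authors. Nuclei of old replicate 1 had no type and were named by clusters, so the source of the names is mixed within the old group. Counts were weighted by inverse document frequency and reduced to 29 components, and Leiden clustering (resolution 1.0) ran on a graph of 30 nearest neighbours. A cluster was named only where its levels over 174 fixed marker genes correlated with an authors' type of the young libraries at 0.4 or more, with a margin of 0.05 over the next type, where at least 3 own markers were detected, and where its 10 leading genes held no more markers of other types than of its own. The markers came in 16 lists fixed before the data were examined: hepatocyte, liver sinusoidal endothelial, vascular endothelial, hepatic stellate, fibroblast, Kupffer, monocyte, dendritic, neutrophil, T, NK, B, plasma, cholangiocyte, erythroid and cycling cells. Clusters led by plasma cell markers were counted with B cells. Names of old replicate 1 read "T-like", "B-like" and so on, and the same clustering was run in the other libraries to check the authors' names. No doublet caller was run. An alternative without the 5% of nuclei with most counts stands in for it.

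Counts were summed per library and cell type, since nuclei are not replicates. A type was tested where each of the 4 libraries had at least 50 nuclei, which left 8 types. The authors' hepatocytes, cholangiocytes, mesenchymal cells, monocyte-derived macrophages and plasmacytoid dendritic cells were not tested, because old replicate 1 had no cluster of those names. Old and young sums were compared with edgeR 4.0.16 (quasi-likelihood test, robust off, TMM scaling, filterByExpr defaults, ~ group) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment within each type and a threshold of 0.05. Fold changes are log2 of old over young, with SE from the quasi-likelihood F. With 2 libraries per age, the lone library of an age in a fit that leaves out another is assumed to vary like the pair. "Groups apart" means that both old values lie on the same side of both young values, which chance gives for 16.7% of genes in 1 direction and 33.3% in either. Fold changes of genes at 0 in every library of an age are given as bounds against 3 counts per library. Bounds and intervals cover counting error only.

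Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01. The same test with an estimated correlation and edgeR fry were set beside it. With an estimated correlation, camera uses the residual degrees of freedom of the 4 libraries, which leaves it little power at any correlation. Benjamini-Hochberg adjustment ran over the 248 tests of lists and types. The 15 lists of processes were AP-1 and immediate early genes, circadian clock, endothelial capillarisation, fibrillar collagen, pericentral and periportal hepatocyte genes, inflammatory chemokines, interferon response, lipid and bile acid metabolism, lipid-associated macrophage, matrix remodelling, senescence, T cell ageing, TGF-beta and myofibroblast activation, and xenobiotic metabolism. Cell type shares were compared by an exact permutation test, two-sided, which cannot go below p = 0.333 with 2 libraries against 2. The difference of the age effect between T and Kupffer cells, the tested types with most nuclei, was tested as an interaction with the library as a block. Peak sets were compared with bedtools 2.31.1 at an overlap of 1 bp.

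The rule for named genes was fixed before the data were examined, as were the lists, markers, tests and most alternatives. Genes with names that begin with Gm and a digit or end in Rik were left out. In T and Kupffer cells the rule took the 10 genes per direction with the smallest adjusted p among those past the threshold with groups apart, and in the other types 4 per direction. Where none passed, it took the 3 per direction with the smallest unadjusted p. For each list it took up to 4 members in the type with the smallest camera p. It also took 3 regions per direction in T and Kupffer cells. It gave 98 genes and 12 regions, of which 1 gene and 1 region are not reported here. Genes named outside it were chosen after their values were seen, and the text says so.

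The gene test of each cell type was run on simulated data made from the real means and library sizes. The fits of regions, of all nuclei and of the interaction were not simulated. The simulated sums held no signal of other cell types and no misnamed nuclei, so rates of wrong calls in the real data can be higher. In each simulation 100 genes were changed by a log2 fold of 1 and 100 by 2, in either direction. Of those at 2, the gene test found 73 in T, 81 in Kupffer, 75 in endothelial, 79 in B, 79 in monocyte, 94 in dendritic, 79 in neutrophil and 74 in NK sums. At 1 it found 46, 47, 21, 57, 50, 77, 31 and 41 in the same order. Calls of unchanged genes were 12 of 131 in T, 19 of 147 in Kupffer, 12 of 108 in endothelial, 15 of 151 in B, 5 of 134 in monocyte, 6 of 177 in dendritic, 6 of 116 in neutrophil and 16 of 131 in NK sums, above 1 in 20 for T, Kupffer, endothelial, B, neutrophil and NK sums.

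Levels of other types' markers were measured in each type as the median ratio of a marker's level in the type to its level in the whole library, over 26 to 41 markers with at least 10 CPM in the library. Alternatives covered DESeq2 1.42.0 size factors and its Wald test, total-count scaling, no filter, other region sets, thinning to equal totals, the replicate number as a block, leaving out each library, and other names of nuclei. The labels give no shared animal, litter or day for a replicate number, and genes of same-numbered libraries did not deviate together (r from -0.45 to -0.04 across types), so the numbers were not taken to pair the libraries. The planned motif test was not run, since the reference used here holds no genome sequence. The planned promoter alternative was not run for lack of strand. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.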

Results

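The study asked how age changes the mouse liver in a preparation digested to enrich the fibrotic niche, with mice of 24 months set against mice of 6 months. Each age had 2 libraries of open chromatin in single nuclei. Old replicate 1 held 20004 nuclei with 217451764 counts in peaks and a median of 9848 counts per nucleus. Old replicate 2 held 8653 nuclei with 200028423 counts and a median of 20380. Young replicate 1 held 3540 nuclei with 101222528 counts and a median of 24373. Young replicate 2 held 6772 nuclei with 137470782 counts and a median of 16134. Old replicate 1 stood apart in that its shallowest nucleus had 6429 counts, against 376, 423 and 369 in the others, and in that the authors' cell types do not cover it. Per library and cell type, the tested sums ranged from 842340 counts (neutrophils of young replicate 2) to 6.54e+07 (Kupffer-like nuclei of old replicate 1).

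The authors called 200059 peaks in old replicate 1, 178945 in old replicate 2, 159337 in young replicate 1 and 163768 in young replicate 2. Libraries of the same age shared 82.9% of their peaks on average and libraries of different ages 75.4%, a difference of 7.5 percentage points. The SD of the same-age overlaps was 3.93 points, but it counts each pair in both directions, so it is not a spread between pairs. Without 1 library the difference ran from 3.94 to 11.3 points. The number of peaks followed the depth, so this overlap does not separate age from depth.

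Endothelial nuclei made up a mean of 7.94% ± 3.27 (SD, n = 2) of the old nuclei and 48.5% ± 9.86 (SD, n = 2) of the young, a difference of -40.5 points. T cells made up 23.5% ± 8.74 of the old and 8.74% ± 3.47 of the young nuclei, and monocytes, the circulating precursors of macrophages, 9.50% ± 1.69 against 2.44% ± 0.0837. Conventional dendritic cells, which present antigen to T cells, made up 11.0% ± 6.59 against 3.63% ± 1.04. For these 4 of 8 types both old libraries lay on the same side of both young ones, which chance gives for 33.3% of types. Shares of a library add up to the whole, so a lower endothelial share raises the others, and these 4 types are not separate observations. Whether T cell, monocyte or dendritic shares rose beyond the endothelial loss was not tested. The exact permutation p was 0.333, the smallest that 2 libraries against 2 can give. Kupffer cells, the resident macrophages of the liver sinusoids, made up 31.2% of old replicate 1 and 1.07% of old replicate 2, against 6.17% and 5.25% of the young replicates. The mean share of Kupffer cells was 10.4 points higher in the old, with a difference of -4.64 points without old replicate 1 and 25.5 without old replicate 2. For B cells the difference was 5.0 points, -1.26 without young replicate 1 and 11.3 without young replicate 2. For neutrophils it was 0.383 points, -1.25 without old replicate 1, 2.02 without old replicate 2, 1.18 without young replicate 1 and -0.413 without young replicate 2. For NK cells it was -0.115 points, -0.269 without old replicate 1, 0.0381 without old replicate 2, -0.761 without young replicate 1, 0.531 without young replicate 2, and 0.689 when all libraries took names from the fixed markers. That of T cells (14.8 points) was 8.57 and that of dendritic cells (7.39) 2.73 without old replicate 2, and the latter 12.1 without old replicate 1. With marker names in every library, an alternative chosen after seeing the data, the difference of T cells was 7.98 points. That naming left 58.3% of the authors' T nuclei of old replicate 2 in unnamed clusters. The same share was 25.1% in young replicate 1 and 28.2% in young replicate 2, so the 7.98 points also reflect this unequal loss. For Kupffer, B, neutrophil and NK nuclei the exact permutation p was 1. Digestion and recovery of nuclei also set such shares. The names came from the fixed markers in old replicate 1 and from the authors elsewhere. In old replicate 2 the markers named 377 of the authors' dendritic nuclei as Kupffer. Counting these as Kupffer gave shares there of 5.45% Kupffer and 11.3% dendritic nuclei, against 1.07% and 15.7%. That alternative was also chosen after seeing the data.

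**Figure D1:**
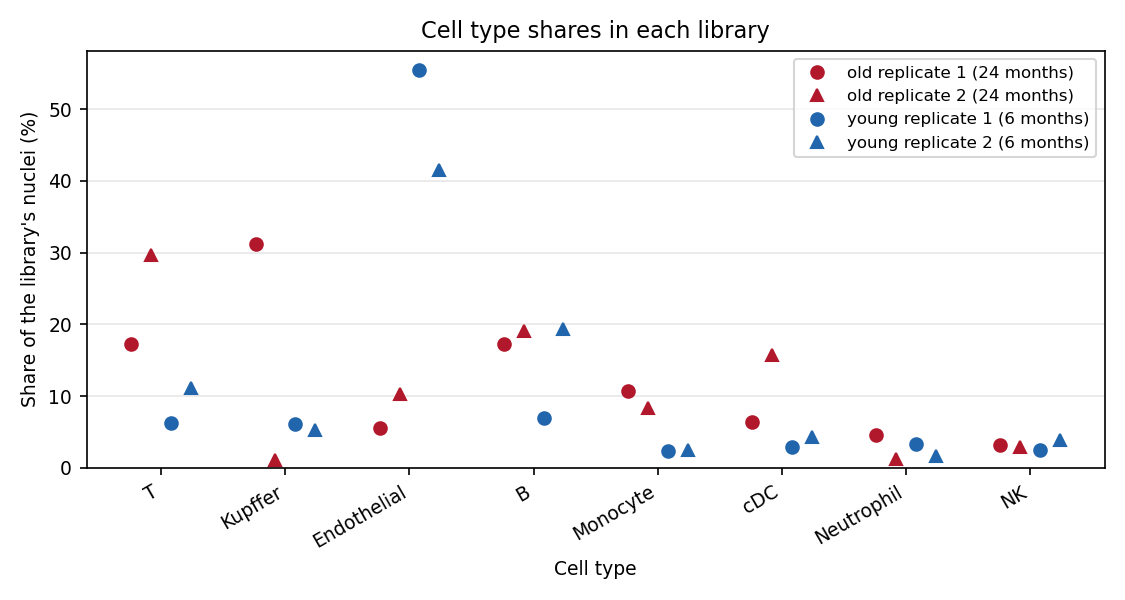
Share of each library's nuclei (vertical axis, percent) by cell type (horizontal axis), with 1 point per library. Endothelial nuclei made up 5.62% and 10.3% of the old libraries and 55.4% and 41.5% of the young.

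Markers of other cell types were read within each type as a measure of how well the nuclei separate. In T cells these markers reached 75.3% of their whole-library level in old replicate 1, against 28.6% in old replicate 2, 18.4% in young replicate 1 and 25.9% in young replicate 2. In Kupffer cells the same measure was 73.4%, against 29.3%, 44.1% and 30.6%, and in NK cells 73.5%, against 27.8%, 8.95% and 15.4%. Old replicate 1 was the highest library in all 8 types tested. The authors' dendritic nuclei of old replicate 2 held 377 of 1351 nuclei (27.9%) in a cluster named Kupffer by the markers, with Timd4, a receptor gene of resident Kupffer cells, among its 10 leading genes. Of the 292 dendritic nuclei of young replicate 2, 114 (39.0%) lay in a cluster named monocyte by the markers, with dendritic cells next, and 167 in an unnamed cluster nearest to dendritic cells, also with Timd4 among its 10 leading genes. In young replicate 1, 98 of 101 lay in a cluster named dendritic. Of the 92 Kupffer nuclei of old replicate 2, 79.3% lay in a cluster with markers of monocyte-derived macrophages.

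**Figure D2:**
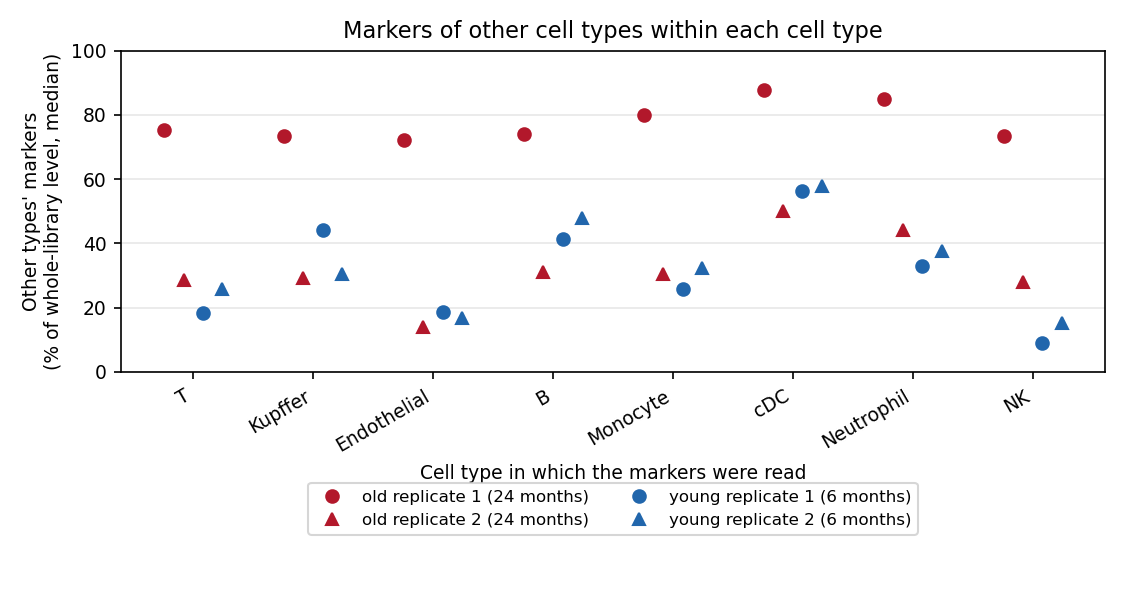
Median level of other cell types' markers (vertical axis, percent of the level in the whole library) within each cell type (horizontal axis), 1 point per library. Old replicate 1 lies between 72.1% and 87.9%, above the other 3 libraries in every type shown.

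In T cells, Plek (chromosome 11, 16971206 to 17008718), which encodes pleckstrin of the immune cell cytoskeleton, rose by a log2 fold of 2.15 ± 0.16 (SE, n = 2 per age, edgeR quasi-likelihood, adjusted p = 0.0227). Its level was 134 and 116 CPM in the old libraries and 25.2 and 30.5 CPM in the young. Plek was the single gene past the threshold of 16155, with 1117 at an unadjusted p under 0.05 and 145 by DESeq2. The call was lost without young replicate 1 (adjusted p = 0.782) or young replicate 2 (0.310). With total counts, or with marker names in every library, 0 genes passed. The marker names left 58.3% of the authors' T nuclei of old replicate 2 unnamed. Over 17 alternatives the adjusted p of Plek ran from 8.44e-32 to 0.782. Of the 17 inflammatory chemokines and cytokines, 15 had a higher level in old T cells, and the list passed camera as higher (median log2 fold 1.41, adjusted p = 0.000362, and adjusted p = 0.839 with an estimated correlation). No member rose over all genes, and 6 rose when adjusted over the list alone. Ccl4, a chemokine that draws T cells and monocytes, was higher by 1.58 ± 0.15 (adjusted p = 0.0528). Ccl3 was higher by 2.08 ± 0.45, Ccl5 by 0.94 ± 0.25 and Il1b by 3.86 ± 1.03, none past the threshold over all genes. The intervals of Ccl3 and Ccl4 overlap, so their counts can share regions and are not separate results. The Il1b level was 37.3 CPM in old replicate 1 and 4.08 in old replicate 2, against 1.03 and 1.65 in the young. Without any 1 library the chemokine list still passed, at an adjusted p of 0.0278 at most. Markers of other types were higher in the same T cell sums. B cell markers passed (median 1.04, adjusted p = 0.00725), though not without old replicate 1 (0.107) or young replicate 1 (0.0689). Monocyte markers passed (median 0.46, adjusted p = 0.0334), though not without old replicate 1 (0.221), young replicate 1 (0.200) or young replicate 2 (0.0729), nor within 1 kb of the gene ends (0.141). These calls were at 0.839 with an estimated correlation. T cell markers themselves passed as lower (median -0.25, adjusted p = 0.0302, and 0.839 with an estimated correlation), and did not pass without old replicate 1 (0.543, pointing higher), young replicate 1 (0.0650) or young replicate 2 (0.111). Neutrophil markers were higher in 6 of 6 members and did not pass (0.102).

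The circadian clock list passed as lower in T cells (median -0.15, adjusted p = 0.0432, and 0.839 with an estimated correlation), and Npas2, a partner of the clock protein BMAL1, fell when adjusted over the list alone (-1.06 ± 0.16). Over all genes it did not pass (adjusted p = 0.296), and Dbp (-0.41 ± 0.17), Nr1d2 (-0.34 ± 0.15) and Cry1 (-0.30 ± 0.15) did not pass. The list did not pass without old replicate 1 (adjusted p = 0.302) or young replicate 1 (0.334), nor within 1 kb of the gene ends (0.0746). Fibrillar collagen and matrix genes passed as higher in T cells (median 0.35, adjusted p = 0.0421, and 0.839 with an estimated correlation). Without old replicate 1 that list pointed lower (adjusted p = 0.803), and without young replicate 1 (0.334) or within 1 kb of the gene ends (0.136) it did not pass. Its Fn1, for fibronectin, was at 0 in both young libraries and at least 5.21-fold higher in the old against 3 counts per library. That bound rests on old replicate 1 (4.31 CPM, against 0.586 in old replicate 2) and is 1.25-fold without it and 9.17-fold without old replicate 2. Vcan was higher by 0.85 ± 0.31, and Col4a2 (1.33 ± 0.61) and Col4a1 (1.04 ± 0.61) had overlapping groups and were at -0.06 and -0.15 without old replicate 1. None of these 4 passed over all genes or adjusted over the list alone. The intervals of Col4a1 and Col4a2 overlap, so their counts can share regions too.

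No region passed in T cells of 94253 tested by edgeR, with 7740 at an unadjusted p under 0.05 and 546 by DESeq2. The smallest p in each direction belonged to a region inside Snx29 (chromosome 16, 11399335 to 11400661), higher by 4.48 ± 0.51 (edgeR adjusted p = 0.129), and to one inside Gria3 (chromosome X, 41400146 to 41401200), at -3.27 ± 0.52 (adjusted p = 0.337). Another higher region lay 16129 bp from Ppp2r2c on chromosome 5 (36849631 to 36850717, 3.90 ± 0.50). Lower ones lay 22297 bp from Trub1 on chromosome 19 (57429605 to 57430595, -3.00 ± 0.48) and 102717 bp from Cd83 on chromosome 13 (43905850 to 43906724, -2.95 ± 0.49). Leaving out old replicate 2 gave 12747 regions and 1570 genes in T cells, old replicate 1 918 and 234, young replicate 1 38 and 0, and young replicate 2 0 and 0.

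In Kupffer cells no gene of 15637 passed by edgeR, with 2173 at an unadjusted p under 0.05 and 410 by DESeq2. Xylt1, an enzyme that starts proteoglycan chains, was higher by 1.94 ± 0.15 (SE, n = 2 per age, edgeR adjusted p = 0.0711), at 171 and 145 CPM in the old against 41.8 and 41.2 in the young. The adhesion gene Dscam (3.80 ± 0.45) and the cytokine gene Clcf1 (1.26 ± 0.17) were also higher. Cpne8 (-3.51 ± 0.33), the matrix signalling gene Ccn1 (-3.91 ± 0.40) and the phosphodiesterase gene Pde10a (-1.48 ± 0.16) were lower. All 6 had groups apart, as chance gives for 33.3% of genes, and none passed (adjusted p = 0.141 to 0.163 for the last 5). Old replicate 2 gave the Kupffer sum only 92 nuclei, and the Ccn1 values there rest on 4 counts and those of Cpne8 on 8. Of these nuclei, 79.3% lay in a cluster with markers of monocyte-derived macrophages and 6.52% in a cluster named Kupffer by the markers. Without old replicate 1, 1037 genes passed, without old replicate 2 4750, without young replicate 1 0, and without young replicate 2 5.

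Endothelial capillarisation and angiocrine genes passed as lower in Kupffer cells (median -0.46, camera adjusted p = 0.00424, and 0.839 with an estimated correlation), and passed without any 1 library. With the Kupffer-marked nuclei of old replicate 2 counted here, an alternative chosen after seeing the data, it did not pass (0.128). Of the 19 members, 6 fell when adjusted over the list alone, among them Bmp6 (-2.09 ± 0.44), Gata4 (-1.97 ± 0.45), Wnt2 (-3.02 ± 0.69) and Plvap (-1.12 ± 0.27), with none past the threshold over all genes. Markers of sinusoidal endothelium also passed as lower there (median -1.03, adjusted p = 0.000362, and 0.839 with an estimated correlation), with 7 of 15 falling when adjusted over the list alone. Of the authors' Kupffer nuclei, 7.41% of young replicate 2, 0.465% of young replicate 1 and 1.09% of old replicate 2 lay in endothelial clusters. Endothelial nuclei made up 48.5% of the young libraries and 7.94% of the old. Whether the endothelial genes fell within Kupffer cells themselves was not tested. Markers of T cells passed as higher (median 2.22, adjusted p = 0.000188, and 0.839 with an estimated correlation), with 8 of 11 rising when adjusted over the list alone. With the Kupffer-marked nuclei counted here, T cell (camera adjusted p = 0.00207), NK cell (0.0122) and sinusoidal endothelial markers (0.00337) still passed. Lipid-associated macrophage genes passed as higher (median 0.45, adjusted p = 0.0161, and 0.839 with an estimated correlation), and did not pass without old replicate 1 (0.0552), old replicate 2 (0.0852) or young replicate 2 (0.0747). After the move of the Kupffer-marked nuclei it did not pass either (0.168), nor within 1 kb of the gene ends (0.131). NK cell markers passed as higher in Kupffer cells (median 2.18, adjusted p = 0.00113), though not without old replicate 1 (0.0925). Monocyte markers passed as higher (median 0.62, adjusted p = 0.0292), though not without old replicate 1 (0.433), young replicate 2 (0.0922) or after the move (0.128). Both lists were at 0.839 with an estimated correlation.

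No region passed in Kupffer cells of 79010 by edgeR, with 12712 at an unadjusted p under 0.05 and 1518 by DESeq2. The smallest p belonged to a region 164392 bp from Efnb2 on chromosome 8 (8451917 to 8452843), at -5.17 ± 0.43 (edgeR adjusted p = 0.105). Regions at H13 and Mcts2 on chromosome 2 (152686485 to 152687416, -4.31 ± 0.47) and at Tcim on chromosome 8 (24438516 to 24439531, -4.44 ± 0.51) were also lower. Higher ones lay inside Shtn1 on chromosome 19 (59036509 to 59037385, 3.35 ± 0.43), inside Runx3 on chromosome 4 (135120011 to 135120916, 5.07 ± 0.67) and on chromosome 17 (45746593 to 45747629, 2.56 ± 0.32). Regions numbered 3518 without old replicate 1, 36 without old replicate 2, 55 without young replicate 1 and 1166 without young replicate 2. The age effect on no gene was found to differ between T and Kupffer cells (0 of 16302 in an edgeR interaction test, 936 at an unadjusted p under 0.05). The interaction gave 2794 genes without old replicate 2, 59 without old replicate 1, and 0 without either young library. DESeq2 was not run for it.

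B cells had 38 genes past the threshold, 28 higher and 10 lower in the old. Il2rb, a chain of the receptors for interleukins 2 and 15, rose by 2.28 ± 0.18 (SE, n = 2 per age, edgeR quasi-likelihood, adjusted p = 0.000272), from 15.4 and 16.3 CPM in the young to 70.0 and 84.3 in the old. Nr3c2, the mineralocorticoid receptor, rose by 1.83 ± 0.16 (adjusted p = 0.000272), the NF-kappaB inhibitor gene Tnip3 by 2.01 ± 0.24 (0.00898) and the transcription factor gene Tfap2a by 1.65 ± 0.22 (0.0156). Fcer2a, which encodes CD23 of follicular B cells, changed by -1.35 ± 0.21 (adjusted p = 0.0286). Medag (-1.21 ± 0.17), Tmem108 (-1.13 ± 0.18) and Epb41l4b (-0.95 ± 0.15) fell likewise. These 8 genes passed without each of the 4 libraries in turn. Of 16018 genes, 1277 had an unadjusted p under 0.05, and DESeq2 called 178. Outside the naming rule, and chosen after their values were seen, Il10 (1.57 ± 0.24) and Zeb2 (0.96 ± 0.17) also rose. Bcl11b, a transcription factor of T cells, rose as well (4.36 ± 0.71), at 42.5 CPM in old replicate 1 and 9.42 in old replicate 2 against 1.07 and 1.37 in the young. Without old replicate 1, 86 genes passed, including 34 of the 38. The counts were 802 without old replicate 2, 132 without young replicate 1 and 596 without young replicate 2, including 38, 35 and 38 of them. With total-count scaling 2 genes passed, both higher.

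Lipid-associated macrophage genes passed as higher in B cells (median 0.57, camera adjusted p = 0.00360, and 0.839 with an estimated correlation). Lgals3 (1.47 ± 0.33), Itgax (1.02 ± 0.29) and Cd9 (0.57 ± 0.19) rose when adjusted over the list alone, and Apoe (0.55 ± 0.23) did not. The list did not pass without old replicate 1 (adjusted p = 0.302) or young replicate 2 (0.0709). The B cell markers passed as lower (median -0.40, adjusted p = 0.000518, and 0.839 with an estimated correlation), with 10 of 10 members lower, 1 falling over all genes and 2 when adjusted over the list alone, and no pass without old replicate 1 (0.0823). Inflammatory chemokines passed as higher (median 1.28, adjusted p = 0.00958, and 0.839 with an estimated correlation), with 5 of 17 rising when adjusted over the list alone, and did not pass without young replicate 2 (0.178). NK cell markers passed as higher in B cells (median 1.32, adjusted p = 0.00224), also without old replicate 1 (0.00237), though not without young replicate 2 (0.0747). Monocyte markers passed as higher (median 0.79, adjusted p = 0.0260), though not without old replicate 1 (0.531), young replicate 1 (0.186) or young replicate 2 (0.0747). Both lists were at 0.839 with an estimated correlation. At region level 400 of 93564 regions passed, 367 higher and 33 lower, with 9199 at an unadjusted p under 0.05 and 812 by DESeq2. The counts were 908 without old replicate 1, 8012 without old replicate 2, 805 without young replicate 1 and 1743 without young replicate 2, all above the count with every library.

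**Figure D3:**
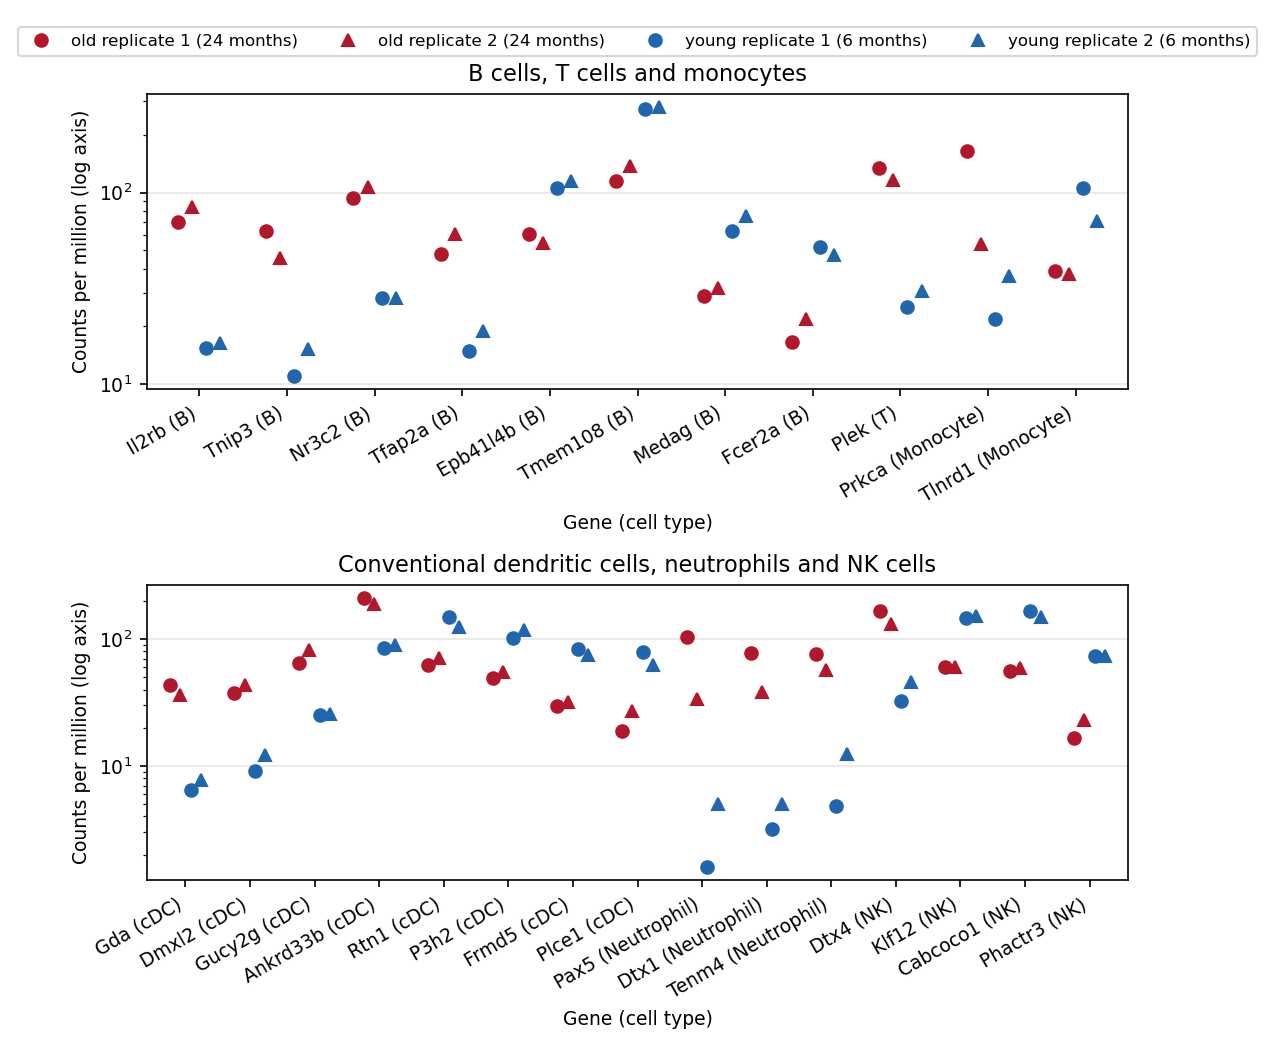
Counts per library of the genes past the threshold that the naming rule picked, in CPM on a log axis, 1 point per library. In B cells Il2rb lies at 70.0 and 84.3 CPM in the old and 15.4 and 16.3 in the young libraries, while Prkca in monocytes and Pax5 in neutrophils are far higher in old replicate 1 than in old replicate 2.

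In conventional dendritic cells 233 genes passed, 110 higher and 123 lower in the old, of 16052 tested. Gda, for guanine deaminase, rose by 2.46 ± 0.26 (SE, n = 2 per age, edgeR quasi-likelihood, adjusted p = 0.00291), from 6.48 and 7.79 CPM in the young to 43.9 and 36.2 in the old. Ankrd33b rose by 1.18 ± 0.13, the guanylate cyclase gene Gucy2g by 1.54 ± 0.17 and Dmxl2 by 1.90 ± 0.24. Frmd5 (-1.35 ± 0.15), the collagen-modifying enzyme gene P3h2 (-1.09 ± 0.13), the phospholipase gene Plce1 (-1.58 ± 0.20) and Rtn1 (-1.04 ± 0.14) fell. These 8 had adjusted p from 0.00291 to 0.00764. None of the 233 passed without young replicate 1 (0 genes), and 26 of them without young replicate 2 (28 genes), against 232 without old replicate 1 (921 genes) and 220 without old replicate 2 (1080 genes). There were 2249 genes at an unadjusted p under 0.05, and 398 by DESeq2.

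Moving the Kupffer-marked nuclei of old replicate 2 out of the dendritic cells, an alternative chosen after seeing the data, left 0 genes past the threshold. The median fold of the genes called higher was 1.12 ± 0.21 (median SE) before and 0.78 ± 0.25 after, and that of the genes called lower -0.81 ± 0.15 before and -0.55 ± 0.19 after. With old replicate 2 as the only old library, these medians were 1.20 ± 0.22 (110 genes) and -0.72 ± 0.17 (123 genes) before the move. After it they were 0.46 ± 0.25 (106 genes) and -0.28 ± 0.16 (123 genes). Leaving out the dendritic nuclei of monocyte-marked clusters, also chosen after seeing the data, gave 405 genes, including 221 of the 233, and 2269 regions. Dendritic cell markers passed camera as lower in these nuclei (median -0.38, adjusted p = 0.000889, and 0.839 with an estimated correlation), with 6 of 11 falling when adjusted over the list alone, and Kupffer markers as higher (0.28, adjusted p = 0.0241, and 0.839). After the move the dendritic markers still passed (adjusted p = 0.00612) and the Kupffer markers did not (0.824). Without old replicate 2 (adjusted p = 0.389) or young replicate 2 (0.144), or within 1 kb of the gene ends (0.0887), the Kupffer markers did not pass either. At region level 1712 of 94612 regions passed, 1232 higher and 480 lower, with 15084 at an unadjusted p under 0.05 and 2009 by DESeq2, and 0 passed after the move. Leaving out old replicate 1 gave 3185 regions, old replicate 2 5673, young replicate 1 2241 and young replicate 2 3825.

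**Figure D4:**
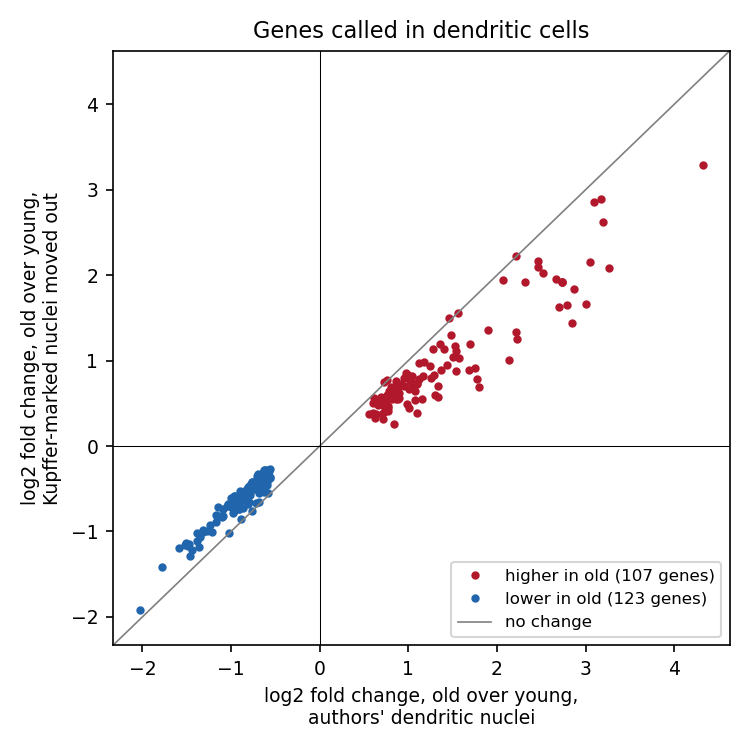
Log2 fold change (old over young) of the genes called in dendritic cells, with the authors' nuclei (horizontal axis) and after the Kupffer-marked nuclei were moved out (vertical axis). Each point is a gene, the line marks equal values, and 107 of the 110 genes called higher had a value after the move.

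In endothelial cells no gene of 16173 passed by edgeR, with 1860 at an unadjusted p under 0.05 and 662 by DESeq2. Zbp1, a sensor of nucleic acids, was higher by 2.39 ± 0.31 (SE, n = 2 per age), the protease inhibitor gene Serpina3n by 1.59 ± 0.28 and the laminin gene Lama2 by 2.46 ± 0.43. Tlnrd1 (-1.10 ± 0.16) and Pcbp3 (-0.80 ± 0.14) were lower. Serpina3n was at -1.21 within 1 kb of the gene ends. All 5 had an edgeR adjusted p of 0.417, and groups apart, as chance gives for 33.3% of genes. There were 6439 genes past the threshold without old replicate 2, 254 without old replicate 1, and 0 without either young library. Capillarisation genes did not pass (median -0.36, camera adjusted p = 0.0520). Sinusoidal endothelial markers passed as lower (median -0.51, adjusted p = 0.00725, and 0.839 with an estimated correlation), though not without old replicate 1 (0.208). Matrix remodelling genes did not pass (adjusted p = 0.125), with Plau (0.82 ± 0.19), Mmp9 (1.15 ± 0.37) and Mmp12 (5.23 ± 1.72) higher and Mmp14 (-0.54 ± 0.18, and 1.20 with regions of matched width) lower, none of them past the threshold. Mmp12 stood at 12.1 CPM in old replicate 1 and 0.426 in old replicate 2, against 0.243 and 0.0797 in the young, and its fold was 1.36 without old replicate 1 (adjusted p = 0.845) and 6.16 without old replicate 2 (7.20e-11). All 4 genes passed without old replicate 2, at an adjusted p of 0.000175 at most. Markers of T cells (median 2.40, adjusted p = 0.00182) and of NK cells (2.26, 0.000995) passed as higher, as did B cell markers (2.21, 0.0495), the last not without young replicate 1 (0.0665) or young replicate 2 (0.0624), nor within 1 kb of the gene ends (0.125). These 3 lists were at 0.839 with an estimated correlation. No region of 97708 passed by edgeR, with 18313 at an unadjusted p under 0.05 and 7665 by DESeq2. Leaving out old replicate 2 gave 59955 regions, old replicate 1 3733, and either young library 0. With total counts in place of TMM the median log2 fold of all endothelial regions moved from 0.21 to 0.71, that of B cells from 0.14 to 0.30, T cells from 0.12 to 0.22, NK cells from 0.12 to 0.23, neutrophils from 0.07 to 0.21 and monocytes from 0.04 to 0.14.

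In monocytes, the kinase gene Prkca rose by 1.85 ± 0.32 (SE, n = 2 per age, edgeR quasi-likelihood, adjusted p = 0.0332) and Tlnrd1 changed by -1.19 ± 0.20 (0.0332), of 15570 genes. Prkca stood at 165 CPM in old replicate 1 and 53.6 in old replicate 2, against 21.9 and 36.5, and did not pass without old replicate 1 (adjusted p = 1). Tlnrd1 did not pass without young replicate 1 (0.0931). With DESeq2 size factors Tlnrd1 alone passed, with total counts 5 genes were higher and 1 lower, and the DESeq2 test called 0 genes and 2 regions. At an unadjusted p under 0.05 stood 945 genes and 3946 of 78541 regions, and edgeR passed 0 regions. Leaving out old replicate 1 gave 1 gene and 15 regions, old replicate 2 542 and 0, young replicate 1 29 and 294, and young replicate 2 169 and 350. T cell markers (median 1.31, adjusted p = 0.00218) and sinusoidal endothelial markers (0.33, 0.0102) passed as higher in monocytes, the latter not without young replicate 2 (0.145). Monocyte markers passed as lower (-0.30, 0.0287), though not without old replicate 1 (0.415), young replicate 1 (0.0689) or young replicate 2 (0.0922). These 3 lists were at 0.839 with an estimated correlation. Within 1 kb of the gene ends the T cell markers (0.0772), sinusoidal endothelial markers (0.340) and monocyte markers (0.113) did not pass.

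In neutrophils, Pax5, the master regulator of B cell identity, rose by 4.55 ± 0.68 (SE, n = 2 per age, edgeR quasi-likelihood, adjusted p = 0.0443). The Notch pathway gene Dtx1 rose by 3.89 ± 0.58 (adjusted p = 0.0443) and Tenm4 by 3.06 ± 0.48 (0.0451). Their young values rest on 2 to 10 counts per library. Without old replicate 1 none of the 3 passed (adjusted p = 0.191 for Pax5, 0.144 for Dtx1 and 0.0504 for Tenm4), and 6 other genes did. Those 3 were among the 403 genes past the threshold without old replicate 2, the 43 without young replicate 1, and the 419 without young replicate 2. There were 1826 genes at an unadjusted p under 0.05 of 13670, and DESeq2 called 33, of them 1 higher and 32 lower, after leaving 12721 genes without an adjusted p. With DESeq2 size factors in edgeR 7 genes were higher and 2 lower. With total counts the median of all genes moved from 0.03 to 0.15. T cell ageing and exhaustion genes passed as higher in neutrophils (median 1.77, or 1.59 with genes at 0 set to their bounds, camera adjusted p = 0.000257, and 0.839 with an estimated correlation). Of the 16 members, 6 rose when adjusted over the list alone and none over all genes. NK cell markers (median 0.89, adjusted p = 0.000638) and T cell markers (1.54, 0.0439) also passed as higher there, both at 0.839 with an estimated correlation, and T cell markers not without old replicate 1 (0.133) or young replicate 1 (0.0650). Within 1 kb of the gene ends the ageing list (0.474), NK (0.261) and T cell markers (0.655) did not pass. Sinusoidal endothelial markers passed as lower (-0.64, adjusted p = 0.00471, and 0.839 with an estimated correlation). Eomes was at least 5.34-fold and Pdcd1 at least 3.76-fold higher against 3 counts per library, Lef1 was higher by 2.54 ± 0.60 and Tox by 2.44 ± 0.64. With marker names in every library Lef1 was at -0.04 and Pdcd1 at -0.67, and 0 genes passed in neutrophils. B cell markers also passed as higher (median 2.00, adjusted p = 0.00113, and 0.839 with an estimated correlation), with 1 of 9 members rising over all genes and 4 when adjusted over the list alone. AP-1 and immediate early genes passed as lower (median -0.54, adjusted p = 0.000902, and 0.839 with an estimated correlation), with Dusp1 (-0.89 ± 0.29), Nr4a1 (-0.78 ± 0.26), Atf3 (-0.87 ± 0.30) and Jund (-0.72 ± 0.28) not passing. That list did not pass without young replicate 1 (0.0581). No region of 32400 passed by edgeR, with 3545 at an unadjusted p under 0.05 and 68 by DESeq2. Regions numbered 0 without old replicate 1, 10 without old replicate 2, 38 without young replicate 1 and 1340 without young replicate 2.

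In NK cells, Dtx4 rose by 1.88 ± 0.21 (SE, n = 2 per age, edgeR quasi-likelihood, adjusted p = 0.0363). Klf12, a transcription factor gene of lymphocytes, changed by -1.32 ± 0.16, Cabcoco1 by -1.45 ± 0.16 and Phactr3 by -1.89 ± 0.22, each with the same adjusted p, and Gm36722 (-1.75 ± 0.20) fell outside the naming rule. These 5 of 14982 genes passed without either old library and did not pass without young replicate 1 (adjusted p = 1.00) or young replicate 2 (0.540). Genes past the threshold numbered 180 without old replicate 1, 1709 without old replicate 2 and 0 without either young library. At an unadjusted p under 0.05 stood 1608 genes, and DESeq2 called 217. NK cell markers passed as lower (median -0.75, camera adjusted p = 0.000334, and 0.839 with an estimated correlation), with 4 of 10 members falling when adjusted over the list alone, and passed without any 1 library. B cell markers passed as higher in the same sums (median 1.14, 9 of 9 higher, adjusted p = 0.0142, and 0.839 with an estimated correlation), though not without old replicate 1 (0.197) or young replicate 1 (0.0581). No region of 57927 passed by edgeR, with 6621 at an unadjusted p under 0.05 and 527 by DESeq2. These numbered 69 without old replicate 1, 10138 without old replicate 2, 468 without young replicate 1 and 637 without young replicate 2.

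Of 248 tests of lists and types, 45 passed camera with the preset correlation, and 0 passed with an estimated correlation or by fry. The loss with an estimated correlation does not by itself show that the genes of a list are correlated. For capillarisation genes in Kupffer cells the estimate was -0.016, below the preset 0.01. Their unadjusted camera p still went from 0.000325 to 0.060. Other lists that passed had estimates far above the preset: 0.555 for AP-1 genes in neutrophils and 0.519 for fibrillar collagen genes in T cells. It was 0.371 for lipid-associated macrophage genes in B cells and 0.326 for circadian genes in T cells. For such lists the preset can make p too small. Of the 45, 17 were lists of processes, 6 were markers of the tested type itself, all lower in the old, and 22 were markers of another type, 20 higher and 2 lower. Some of the 17 are named for another cell type than the one tested. Examples are T cell ageing genes in neutrophils, endothelial capillarisation genes in Kupffer cells and lipid-associated macrophage genes in B cells. The 22 therefore do not count every list of another type's genes. T cell ageing genes also passed as higher in endothelial cells (adjusted p = 0.00564), monocytes (0.00224), B cells (0.00958) and Kupffer cells (0.0158). Without old replicate 1 they did not pass in monocytes (0.158) or Kupffer cells (0.399), nor in monocytes without young replicate 2 (0.218), nor in Kupffer cells after the move (0.117) or within 1 kb of the gene ends (0.142). They did not pass in T cells themselves (0.155), where 6 of 17 rose when adjusted over the list alone. AP-1 genes passed as lower in endothelial cells (0.0271), monocytes (0.0302) and T cells (0.0318), though in none of these without old replicate 1 (0.113, 0.433 and 0.392) or young replicate 1 (0.166, 0.516 and 0.555), nor within 1 kb of the gene ends (0.0857, 0.131 and 0.296), nor in T cells with the replicate block (0.0517). Circadian genes passed as lower in endothelial cells (0.0495), though not without old replicate 1 (0.203), old replicate 2 (0.112) or young replicate 1 (0.200), nor within 1 kb of the gene ends (0.0887) or with the replicate block (0.0733). All these calls had an adjusted p of 0.839 with an estimated correlation. The smallest adjusted p of the lists that passed in no type was 0.163 for interferon response (monocytes), 0.154 for lipid and bile acid metabolism (endothelial cells), 0.125 for matrix remodelling, 0.202 for senescence (B cells), 0.308 for TGF-beta and myofibroblast activation (neutrophils), 0.392 for xenobiotic metabolism (NK cells), 0.264 for periportal (endothelial cells) and 0.473 for pericentral hepatocyte genes (B cells). Among their members, Ciita (0.73 ± 0.20) in monocytes, Lmnb1 (0.62 ± 0.17) in B cells and Abcc2 (2.72 ± 0.79) in NK cells rose when adjusted over the list alone, and these 3 did not rise over all genes. H2-Eb1 (0.58 ± 0.19) and Ifit1 (1.32 ± 0.56) in monocytes, Nr1h4 (0.83 ± 0.24) and Fasn (0.51 ± 0.16) in endothelial cells, and Tgfbr1 (-0.78 ± 0.26) and Acta2 (-0.86 ± 0.29) in neutrophils did not pass either way. Outside the naming rule, Timp2 rose over all genes in B cells (1.14 ± 0.20, adjusted p = 0.0436, and 0.0358 at most without any 1 library). In dendritic cells Timp2 (1.25 ± 0.21, adjusted p = 0.0150) and Acta2 (1.07 ± 0.21, 0.0330) rose, and Adamts2 (-1.15 ± 0.19, 0.0150) and Ccn2 (-1.44 ± 0.31, 0.0447) fell. These 4 did not pass without young replicate 1 (0.149, 0.262, 0.120 and 0.405) or after the move (0.573, 0.687, 0.554 and 0.446), and only Timp2 passed without young replicate 2 (0.0442, against 0.173, 0.150 and 0.147). With marker names in every library Ciita was at -0.11 and H2-Eb1 at -0.16, and 0 genes passed in monocytes. Of the marker lists not named above, monocyte markers passed as higher in endothelial cells (0.00100), fibroblast markers as higher in NK cells (0.0483) and cholangiocyte markers as higher in endothelial cells (0.0495), each at 0.839 with an estimated correlation. The fibroblast list did not pass without old replicate 1 (0.127), young replicate 1 (0.0549) or young replicate 2 (0.0922), nor the cholangiocyte list without old replicate 1 (0.208) or old replicate 2 (0.0616). Within 1 kb of the gene ends neither passed (0.173 and 0.355), nor did the fibroblast list with the replicate block (0.0508). In no type did the lists of stellate cells (0.0935 at the lowest), neutrophils (0.102), plasma cells (0.116), vascular endothelium (0.145), cycling cells (0.171), hepatocytes (0.193) or erythroid cells (0.274) pass.

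Over all nuclei, with the mix of cell types left in, 19004 of 109525 regions passed, 6620 higher and 12384 lower in the old. With total-count scaling 12280 were higher and 10670 lower, and the median of all regions moved from 0.17 to 0.38. With regions that had a peak in 2 or more libraries, 21502 were higher and 12534 lower. Leaving out old replicate 1 gave 7241 regions, young replicate 1 11630 and young replicate 2 29174. At an unadjusted p under 0.05 stood 38941 regions, and DESeq2 called 23306. Endothelial nuclei made up 48.5% of the young libraries and 7.94% of the old, so these calls are not those of any 1 cell type.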

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

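All tests of explanations in this part were chosen only after the results they address were seen.

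Signals outside the comparisons were found in 4 places. In the 3 libraries with the authors' cell types, 187 barcodes had counts in peaks and no type (40 in old replicate 2, 55 in young replicate 1 and 92 in young replicate 2), with a median of 524 counts. In old replicate 1, 762 nuclei (3.81%) lay in a cluster that no marker list names. A pair of peak lists that belong to no sample of the series hold 33769 and 25870 positions. They use 10 chromosome names, and of their positions on chromosome 1, 2297 of 5203 and 1648 of 4197 lie past the end of the last mouse gene there (195176880), so they are not on the mouse genome and were not analysed here.

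Dendritic cells gave 233 genes past the threshold, and after 377 Kupffer-marked nuclei of the 1351 in old replicate 2 were moved, 0 genes passed by edgeR, with median folds of 1.12 ± 0.21 before and 0.78 ± 0.25 after for genes called higher, and -0.81 ± 0.15 and -0.55 ± 0.19 for genes called lower. The move changes old replicate 2 alone. With it as the only old library the medians were 1.20 ± 0.22 (110 genes) and -0.72 ± 0.17 (123 genes) before the move. After it they were 0.46 ± 0.25 (106 genes) and -0.28 ± 0.16 (123 genes), with the sign kept by 98 and 118 of these genes. Each SE is the median of single genes, so it does not show whether a set lies near 0. These nuclei may account for the calls, and whether they account for the folds of that library cannot be told. The genes were called with old replicate 2 among the libraries, which favours genes on which both old libraries agree. The 1.20 without old replicate 1 is thus in part set by that choice and does not decide on carry-over there. The nuclei in old replicate 2 and carry-over in old replicate 1 together also stay open. A library-wide profile subtracted left 0 genes at folds too noisy to decide (1.40 ± 2.01 for 51 genes called higher and -0.52 ± 0.50 for 122 called lower). Without the nuclei of monocyte-marked clusters (114 of 292 in young replicate 2), 405 genes passed, including 221 of the 233, so the calls do not rest on those. The gene calls were also lost without young replicate 1, where the folds hardly moved (1.09 ± 0.27 and -0.81 ± 0.19) and 2241 regions passed, and an effect of age, untested apart from these libraries, stays open.

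B cells gave 38 genes, and old replicate 1, the library with the highest level of other types' markers, is a candidate source of such calls. Without it the median of the genes called higher was 1.65 ± 0.26, against 1.66 ± 0.24 with it, so their folds did not rest on old replicate 1 alone. The genes were called with old replicate 2 among the libraries, which favours genes on which both old libraries agree. That median is thus in part set by the choice of genes, and carry-over in old replicate 1 as a source of the calls stays open. With a library-wide profile subtracted, 0 genes passed: the 20 of 28 genes called higher that remained in the test went from 1.51 ± 0.21 to 3.23 ± 1.14, and the 10 called lower from -1.07 ± 0.17 to -1.10 ± 0.19. For the latter fold and SE hardly moved, and the prior degrees of freedom of the fit fell from 10.8 to 3.30, which raises p at the same ratio of fold to SE. Single genes such as Bcl11b, nuclei of other types in old replicate 2 (NK markers passed as higher without old replicate 1, adjusted p = 0.00237), a change of B cells with age and the mixed source of the names stay open.

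Markers of other types were at their highest in old replicate 1 in 8 of 8 tested types, but this level is itself the measure of separation, so it does not test weak separation of cell types in that library as an explanation. Carry-over in proportion to the share of the source type was tested only in old replicate 2 against the young libraries. There 50% of pairs of a type and a marker list (17 of 34) moved the way of the share. The pairs of NK markers were scored on a share change of only -0.13 log2. Those of Kupffer markers rest on the authors' 92 Kupffer nuclei of old replicate 2. Sinusoidal markers in Kupffer cells were not among the pairs. The 50% therefore does not decide the explanation in old replicate 2, and it decides nothing for old replicate 1. In old replicate 2 the level was below both young libraries in Kupffer (29.3% against 44.1% and 30.6%), endothelial (13.9% against 18.8% and 16.7%), B (31.1% against 41.5% and 48.0%) and dendritic sums (49.98% against 56.4% and 58.0%), between them in monocytes, and above both in T, NK and neutrophil sums. Single lists were higher in the old without old replicate 1 too: T (adjusted p = 0.00140), NK (0.000101), monocyte (0.000307) and B cell markers (0.0245) in endothelial cells, T cell markers in Kupffer cells (0.00389) and monocytes (0.0144), and NK (0.00342) and B cell markers (0.00752) in neutrophils. These values are from camera with the preset correlation. With every library and an estimated correlation, each of these lists was at an adjusted p of 0.839. For the level in old replicate 1, mixed nuclei, less exact names and a different choice of barcodes (its shallowest nucleus had 6429 counts) cannot be told apart, and age stays open, as 1 other old library does not show a rise in every type.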

How the results depend on the processing

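The crossed replicate numbers, the moved Kupffer-marked nuclei, the left-out monocyte-marked nuclei, the marker names in every library, the 1 kb gene ends and the subtracted carry-over were chosen after seeing the data, and the other alternatives before. The promoter alternative and the motif test were not run, for lack of strand and of a genome sequence. The marker names gave no dendritic nuclei in young replicate 2, so they give no value there, and DESeq2 was not run for the interaction. Of the counts, shares and list totals, 169 combinations of result and alternative kept their direction and side of the threshold (for counts, stayed within 1.5 times), 85 moved, 64 came past the threshold, 28 no longer passed and 7 reversed. Of the named genes, regions and lists, 1652 stayed, 206 came past the threshold, 231 no longer passed and 16 reversed. Where no reason is given below, the cause was not tested.

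Region counts with every library were 0 in T, Kupffer, endothelial, monocyte, neutrophil and NK sums, 400 in B, 1712 in dendritic cells and 19004 over all nuclei. The DESeq2 Wald test gave 546 in T, 1518 in Kupffer, 7665 in endothelial, 812 in B, 2 in monocyte, 68 in neutrophil and 527 in NK sums. With no filter on low counts there were 723 in T, 246 in Kupffer, 2250 in B, 245 in monocyte, 151 in neutrophil and 1274 in NK sums. Thinned to the smallest total, T had 1, B 676, monocytes 1 and NK 8. Without the top 5% of nuclei by counts, B had 811, dendritic cells 668 and NK 3. With regions with a peak in 2 or more libraries, B had 0, dendritic cells 0, neutrophils 1 and all nuclei 34036. Such regions have structural 0 counts in libraries without the peak. Total counts gave 213 in B. With the replicate number as a block, T had 285, Kupffer 950, endothelial 1249, B 977, dendritic 2876, neutrophil 22 and NK 161. After the Kupffer-marked nuclei were moved, Kupffer cells had 1 and dendritic cells 0, or 42 with old replicate 2 as the only old library. With marker names in every library, Kupffer had 69, endothelial 5157, B 719 and NK 273.

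Gene counts with every library were 1 in T, 0 in Kupffer, 0 in endothelial, 38 in B, 2 in monocyte, 233 in dendritic, 3 in neutrophil and 5 in NK sums. With DESeq2 size factors T had 3, monocytes 1 and neutrophils 9. With total counts T had 0, B 2, monocytes 6 and NK 0. The DESeq2 Wald test gave 145 in T, 410 in Kupffer, 662 in endothelial, 178 in B, 0 in monocyte, 398 in dendritic, 33 in neutrophil and 217 in NK sums. With no filter on low counts monocytes had 46, neutrophils 42 and NK 46. With regions of matched width monocytes had 0 and neutrophils 20. With regions with a peak in 2 or more libraries T had 2, Kupffer 1, monocytes 0, dendritic cells 59, neutrophils 0 and NK 0. Thinned to the smallest total, T had 2, Kupffer 1, B 14 and monocytes 0. Without the top 5% of nuclei T had 4, monocytes 12, dendritic cells 64, neutrophils 151 and NK 9. With the replicate block T had 105, Kupffer 518, B 131, monocytes 34, neutrophils 207 and NK 309. After the move Kupffer cells had 49 and dendritic cells 0, or 20 with old replicate 2 as the only old library. Without monocyte-marked nuclei dendritic cells had 405. With marker names in every library T had 0, Kupffer 31, monocytes 0, neutrophils 0 and NK 39, and B 35, all of them among the 38. Within 1 kb of the gene ends T had 0, B 78, monocytes 4, dendritic cells 77, neutrophils 39 and NK 2. With carry-over subtracted T, B, monocytes, dendritic cells, neutrophils and NK had 0. The 45 lists past the threshold with a preset correlation were 0 with an estimated correlation.

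Replicate numbers name no shared animal or day, so the block has no known meaning here. Crossing the numbers gave region counts of 2429 in T, 12952 in endothelial, 3820 in B, 526 in monocyte, 4258 in dendritic, 19 in neutrophil and 3714 in NK sums, and gene counts of 74 in Kupffer, 346 in B, 167 in monocyte, 540 in dendritic, 16 in neutrophil and 1040 in NK sums.

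Leaving out 1 library gave region counts of 0 to 12747 in T, 36 to 3518 in Kupffer, 0 to 59955 in endothelial, 805 to 8012 in B, 0 to 350 in monocyte, 2241 to 5673 in dendritic, 0 to 1340 in neutrophil and 69 to 10138 in NK sums, and 7241 to 29174 over all nuclei. Gene counts ran from 0 to 1570 in T, 0 to 4750 in Kupffer, 0 to 6439 in endothelial, 86 to 802 in B, 1 to 542 in monocyte, 0 to 1080 in dendritic, 6 to 419 in neutrophil and 0 to 1709 in NK sums. Lists past the threshold ran from 29 to 75 and interaction genes from 0 to 2794. In these fits the lone library of an age is assumed to vary like the other age's pair. Differences in share ran, in percentage points, from 8.57 to 20.9 for T, -4.64 to 25.5 for Kupffer, -47.5 to -33.6 for endothelial, -1.26 to 11.3 for B, 5.86 to 8.26 for monocyte, 2.73 to 12.1 for dendritic, -1.25 to 2.02 for neutrophil and -0.761 to 0.531 for NK nuclei, and the gap in peak overlap from 3.94 to 11.3. The shares reversed were Kupffer (-4.64 without old replicate 1), B (-1.26 without young replicate 1), neutrophil (-1.25 without old replicate 1, -0.413 without young replicate 2) and NK (0.0381 without old replicate 2, 0.531 without young replicate 2, and 0.689 with marker names in every library).

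Single results reversed as follows, none past the threshold where its sign was reversed. Within 1 kb of the gene ends, Serpina3n in endothelial cells was at -1.21, Ciita in monocytes at -0.33 and Isg15 there at 0.23, and T cell markers in neutrophils pointed lower (adjusted p = 0.655). With regions of matched width, Mmp14 was at 1.20 in endothelial cells. With carry-over subtracted, Glul was at 0.066 and Itgax at -0.014 in B cells and H2-Eb1 at -0.68 in monocytes. With marker names in every library, Ciita was at -0.11 and H2-Eb1 at -0.16 in monocytes, and Lef1 at -0.040 and Pdcd1 at -0.67 in neutrophils. Leaving out 1 library put Col4a2 in T cells between -0.063 (without old replicate 1) and 1.99 (without old replicate 2), and Col4a1 between -0.15 and 1.67 in the same fits. The adjusted p of fibrillar collagen genes in T cells ran from 0.000776 (higher, without old replicate 2) to 0.803 (lower, without old replicate 1), and that of T cell markers there from 3.31e-06 (lower) to 0.543 (higher) in the same fits.

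On simulated data a log2 fold of 1 was found for 21 of 100 genes in endothelial cells, 31 in neutrophils, 47 in Kupffer cells and 77 in dendritic cells. This order is not that of depth: endothelial sums, among the deepest, had the largest biological coefficient of variation (0.323), and the shallowest sum was that of neutrophils in young replicate 2 (842340 counts from 114 nuclei). Fewer genes were tested in neutrophils (13670) than in T cells (16155). Calls of unchanged genes made up 19 of 147 calls in Kupffer, 16 of 131 in NK, 15 of 151 in B, 12 of 131 in T and 12 of 108 in endothelial sums, so single calls near the threshold are less firm than it states.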

Other observations

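The comparisons across cell types and the genes named in this part were chosen only after the results were seen.

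In Kupffer cells, counting the Kupffer-marked nuclei of old replicate 2 raised the sum there from 92 to 469 nuclei, and their share of that library to 5.45%. With that alternative, 49 genes passed by edgeR, 19 higher and 30 lower in the old. The smallest adjusted p belonged to Sh3bp4 (-2.22 ± 0.12, 0.0121), and Arhgef10 (1.81 ± 0.12) was at 0.0175. Tnip3 (2.01 ± 0.17), Clcf1 (1.34 ± 0.14), Pde10a (-1.69 ± 0.14) and Cpne8 (-3.39 ± 0.30) also passed. Markers of T cells (camera adjusted p = 0.00207) and NK cells (0.0122) still passed as higher and sinusoidal endothelial markers (0.00337) as lower. The authors' 92 nuclei stay in this sum, and 79.3% of them lay in a cluster with markers of monocyte-derived macrophages. The alternative was not run without single libraries, so whether the 49 genes rest on 1 library was not tested.

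Across the 8 tested types, Fiz1 had an unadjusted p under 0.05 and groups apart, lower in the old, in 8 of 8, and A530032D15Rik, higher in the old, in 8 of 8. Tuba1b was lower in this sense in 7 of 8. Bcl11b, Mdfic and Rap1gap were higher in 7 of 8. In B, endothelial, Kupffer, monocyte, neutrophil and dendritic sums Bcl11b stood at 42.5 to 53.7 CPM in old replicate 1. In old replicate 2 it stood at 8.86 to 18.8 CPM there. In NK sums it was at 78.1 and 86.4 CPM, and in T cells its fold was -0.22 ± 0.28. A530032D15Rik was higher in old replicate 1 than in old replicate 2 in every type but B cells (55.7 against 83.8 CPM). Whether carry-over in old replicate 1 made these rises was not tested. The types come from the same 4 libraries, so these are not independent repeats, and no test across types was run.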
